A study of Homo sapiens with 4 samples.

How the data were processed

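Total RNA from AGS cells, an established human gastric adenocarcinoma line, was profiled on Affymetrix Human Gene 1.0 ST arrays. The 4 arrays fall into 2 groups of 2 biological replicates, cells given 0.01% ornithogalum and cells given ethanol as vehicle, each for 36 h. The deposited table holds a log2 expression value per array and transcript cluster (a set of probes covering 1 transcript locus), made by the authors with robust multi-array average (RMA) in Affymetrix Expression Console 1.1 per the submitters' processing notes. Background, quantile and filter settings are not given in the sources used here. The 4 columns do not share a distribution, so a common quantile scaling over exactly these clusters is not what they show. No depth applies to arrays, and the number of arrays limits the precision.

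The table has 33297 clusters. Names came from the platform annotation of 2016, in which 19461 clusters have 1 gene symbol, 1753 have several and 12083 have none in the table used here. Symbols were updated through the gene number in the RefSeq gene table, which matched 19429 clusters. The 21214 clusters with at least 1 symbol were tested, with no filter on dim clusters. No gene was named from a cluster with several symbols. For gene lists, each of 18418 genes was represented by its cluster of highest mean log2 value. Of 769 genes with several such clusters, 3 had clusters called in opposite directions.

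Groups were compared on the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. "Higher", "lower", "rose" and "fell" refer to ornithogalum relative to vehicle and to an adjusted p under this threshold. Means are given with the SD over 2 arrays and differences with limma's SE. Fold changes are 2 raised to the log2 difference. The replicates are biological replicates per the labels, which do not say whether they came from separate experiments, so p-values measure the spread between these samples only. A count without a test took clusters whose arrays in a group all lay at least 1.5-fold beyond those of the other group, and was repeated for the other 2 splits of the 4 arrays, each of which mixes the treatments. With 2 arrays against 2 there are 3 splits, too few for a share under 0.05.

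Before the data were examined, 32 gene lists were fixed for this cell type and treatment, among them markers of fibroblasts, leukocytes, and endothelial and erythroid cells. They hold 685 entries, of which 616 were measured after 30 older symbols were updated. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists, with an estimated correlation and with fry as alternatives. With an estimated correlation camera tests on the 2 residual degrees of freedom, so it has far less power whatever the correlation. Each list's median was also set against 10000 random lists matched on mean log2 value in 20 bins. The genes named were chosen by a rule fixed at the same time. Among called clusters with 1 symbol and no overlap between groups, it takes the 12 largest rises and the 12 largest falls. It adds the 3 members of smallest p from each list called by camera or with called members, and at most 2 from other lists. Not all of these list members are named below. Other genes named were chosen after their values were seen.

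The fitting code was tested on simulated data with the pooled spread of these arrays, the same in both groups. In 20 runs with 200 of 21214 clusters changed, limma recovered 0.149% of the changes of 1.5-fold, 4.85% of those of 2-fold and 83.3% of those of 4-fold, with 3.9 wrong calls per run on average. With the 4076 clusters called here changed by their measured differences it recovered 73.6%, and 4.06% of its calls were false. Those differences come from clusters already called, so this recovery describes changes selected for being called. The p53 list, with all members raised 2-fold on purpose, was called in 20 of 20 runs, with 0.25 wrong lists per run. These rates hold for groups of equal spread and independent clusters. In these data the SD within groups was 0.258 for ornithogalum and 0.140 for vehicle, so the true rates can differ.

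Settings fixed before the data were examined were the replicate number as a block, leaving out each array, quantile, cyclic loess and median scaling, brighter clusters only, an intensity trend with and without a robust prior, other sets of clusters, no moderation, and other thresholds. Array weights were added as 1 further setting after the ornithogalum arrays were seen to differ more from each other than the vehicle arrays did. After the ranked changes had been read, 13 further gene families were drawn up. All 13 are reported in the closing section and adjusted together, with the membership in which they were first looked at. Changes were also viewed by gene length, gene type and chromosome, and only gene length was carried further. Of 9 tests of explanations, 2 had their bounds written before their outcome was seen and 7 after. The test of the first ornithogalum array's distribution first used the count without that array, and was replaced by quantile scaling once that count was seen to depend on which pair gives the spread. The test of unequal distributions as a cause of the excess of lower clusters was first decided without median centring, and was left undecided once it was taken in. The bound for markers of other cell types was first set on the deposited values alone. With scalings added it was read for a time without regard to the median of all clusters, which left it undecided, and then relative to that median, because centring moves all clusters alike.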

Results

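Expression was measured in AGS gastric cancer cells after 36 h with 0.01% ornithogalum, a homeopathic formulation, or with its ethanol vehicle, on 2 arrays per group. The comparison asks which transcripts differ in level between treated and vehicle cells. The median log2 value over named clusters was 4.48 and 4.62 on the ornithogalum arrays and 4.71 and 4.70 on the vehicle arrays, and the interquartile range was 2.44 and 2.56 against 2.72 and 2.71. Across clusters, which are not independent replicates, Pearson's r was 0.995 between the vehicle arrays, 0.981 between the ornithogalum arrays and 0.947 to 0.961 between groups.

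**Figure D1:**
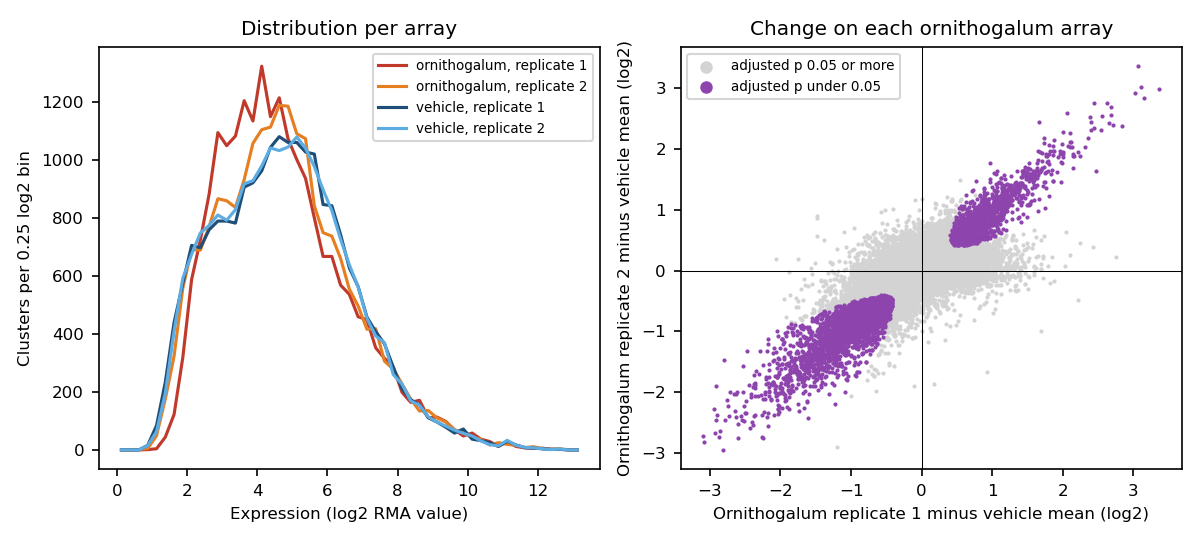
Left, number of named clusters per bin of log2 expression value, with a line per array. Right, each cluster's log2 difference from the vehicle mean on ornithogalum array 1 (x) and array 2 (y), with called clusters in purple. The first ornithogalum array has the narrowest distribution (interquartile range 2.44), and the differences on the 2 arrays correlate at r = 0.803.

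The largest rises in ornithogalum-treated cells included stress-response and clock genes, and the largest falls included metabolic and interferon-induced genes. RIMKLB, an amino acid ligase, rose most, 9.28-fold (log2 difference 3.21, SE 0.18), from 4.16 ± 0.25 to 7.38 ± 0.22 (SD, n = 2 per group). NR1D1, a repressor in the circadian clock, rose 9.04-fold (3.18, SE 0.16), and the clock gene PER1 rose 6.11-fold. PPP1R15A, which directs dephosphorylation of the translation factor eIF2-alpha, rose 7.94-fold from 6.11 ± 0.21 to 9.10 ± 0.22. GDF15, a stress-induced cytokine, rose 6.42-fold and GADD45A, a growth-arrest gene, 6.46-fold.

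The other 6 of the 12 largest rises were in the arrestin-domain gene ARRDC3 (8.36-fold), MOSPD1 (7.84-fold), the ubiquitin ligase LNX1 (6.15-fold), the transcription factor THAP1 (6.07-fold), CREBRF (5.87-fold) and PHLDA1 (5.87-fold). IDH1, the cytosolic isocitrate dehydrogenase, had the largest fall, 7.71-fold (log2 difference -2.95, SE 0.14), from 9.28 ± 0.020 to 6.33 ± 0.19. PRR15L fell 7.37-fold, the apolipoprotein gene APOL1 6.99-fold, the pseudokinase gene STRADB 6.95-fold and the interferon-induced helicase gene DDX60 6.74-fold. A second STRADB cluster, with a larger p, had a log2 difference of -2.91. Whether the probes of these STRADB clusters overlap was not checked, so the second is not independent support. TIMMDC1, an assembly factor of respiratory complex I, fell 6.43-fold and CBR4, a mitochondrial reductase, 6.43-fold. SYTL2, HPS3, RNF170 and the gasdermin gene GSDMB fell 6.23-fold, 6.17-fold, 6.08-fold and 5.93-fold. The pseudogene AMZ2P1 fell 5.92-fold, and its parent gene AMZ2, looked up afterwards, fell 3.63-fold, and whether their probes overlap was not checked, so the source of that signal is uncertain. Over these 24 genes limma's adjusted p lay between 0.00336 and 0.00449. Each gene moved the same way on both ornithogalum arrays by the rule that chose them, so this is no separate support.

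**Figure D2:**
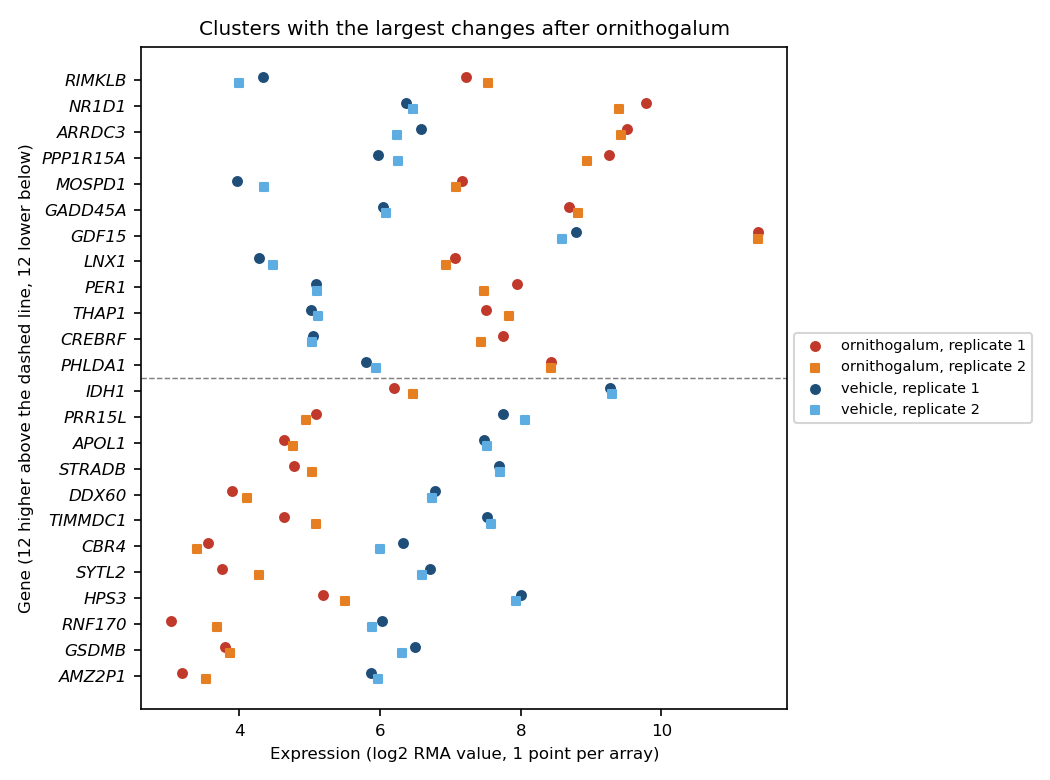
Log2 expression value (x) of the 12 genes with the largest rise and the 12 with the largest fall (y), with a point per array. The groups do not overlap for any of them, by the rule that chose them, and the folds run from 5.87 to 9.28 for rises and from 5.92 to 7.71 for falls.

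Of 21214 clusters tested, limma called 4076 (19.2%), 1393 higher and 2683 lower, with a median change of 1.82-fold. At least 2-fold changes were called in 1538 clusters, 415 higher and 1123 lower. At an unadjusted p under 0.05 there were 7160 clusters, against 1060.7 by chance. The groups were apart by at least 1.5-fold in 2683 clusters, 831 higher and 1852 lower, against 10 in each of the other 2 splits of the arrays. Those splits put a treated array on each side, so a treatment difference keeps their counts low and they do not show what no effect would give. The groups did not overlap in 62.2% of clusters, where chance gives 33.3%. Each ornithogalum array's difference from the vehicle mean correlated across clusters at r = 0.803 with the other's, where a simulation with no effect and the shared vehicle arrays gave 0.125, and the covariance was 0.258 against 0.0096. The calls rested on the spread of the vehicle pair, since without vehicle replicate 1 or 2 limma called 0 clusters, with 4192 and 3986 at an unadjusted p under 0.05, and without ornithogalum replicate 2 it called 7058. The excess of lower calls depended on the scaling, because centring each array on its median, which moved the median of all differences from 0.035 to 0.195, gave 2238 higher and 1898 lower.

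Immediate early genes, which respond to signals within minutes to hours, rose together. Of 23 measured, 18 rose and 0 fell (19 and 0 adjusted over the list alone), with a median log2 difference of 1.26. DUSP1, a phosphatase of MAP kinases, rose 4.25-fold, the nuclear receptor NR4A2 3.70-fold and the AP-1 gene JUNB 4.09-fold. Camera gave an adjusted p = 2.9e-12, and adjusted p = 0.41 with an estimated correlation. Targets of the tumour suppressor p53 also rose, 14 of 21 measured, while 1 fell (15 and 3 adjusted over the list alone), with a median of 1.02. They included GDF15, the death receptor genes FAS (3.54-fold) and TNFRSF10B (3.14-fold) and, chosen after their values were seen, CDKN1A (2.09-fold) and MDM2 (1.45-fold), while CCNG1 was the member that fell (1.70-fold). For this list camera gave an adjusted p = 1.3e-05, and adjusted p = 0.41 with an estimated correlation.

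Chaperones and folding factors of the endoplasmic reticulum made up the third higher list, the unfolded protein response. Of 17 measured, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.30, and HERPUD1 rose 2.62-fold, HSPA5 2.52-fold and DNAJC3 3.12-fold. Camera gave an adjusted p = 0.00021 for it, and adjusted p = 0.55 with an estimated correlation.

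Type I interferon response genes were lower. Of 28 measured, 0 rose and 14 fell (0 and 15 adjusted over the list alone), with a median of -0.68, and DDX60 fell 6.74-fold, PARP9 5.56-fold and the antiviral GTPase gene MX2 5.72-fold. Camera gave an adjusted p = 0.00013 here, and adjusted p = 0.41 with an estimated correlation. Genes of glycolysis and the hypoxia response fell in 12 of 23 measured and rose in 0 (13 and 2 adjusted over the list alone), with a median of -0.58. PGK1 fell 2.32-fold, PDK1, a kinase that restrains pyruvate dehydrogenase, 2.78-fold and ALDOC, an aldolase, 2.75-fold. For glycolysis camera gave an adjusted p = 0.0011, and adjusted p = 0.55 with an estimated correlation. The estimated correlation was -0.0028 for the interferon and -0.035 for the p53 list, below the preset 0.01. A higher correlation is thus not what removed those calls. It was 0.043 for the immediate early, 0.058 for the glycolysis and 0.16 for the unfolded protein response list, above the preset. Camera with an estimated correlation also has only 2 residual degrees of freedom, so the loss of these calls is no evidence of correlated genes. Among 10000 random lists matched on mean log2 value, 0 had a median as high as the immediate early or p53 lists, 0 as low as the interferon list, 1 as low as the glycolysis list and 145 as high as the unfolded protein response list. Of lists that camera did not call, 24 random lists were as low as the histone list, 300 as low as the intestinal list, 100 as high as the NF-kappaB list and 275 as high as the MYC list. Without the first ornithogalum array, which had the narrowest distribution, camera called the same 5 lists in the same directions. Without the second, 2 p53 targets fell instead of 1, and 2 glycolysis genes and 1 interferon gene rose instead of 0, while 1 glycolysis gene rose without the first.

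**Figure D3:**
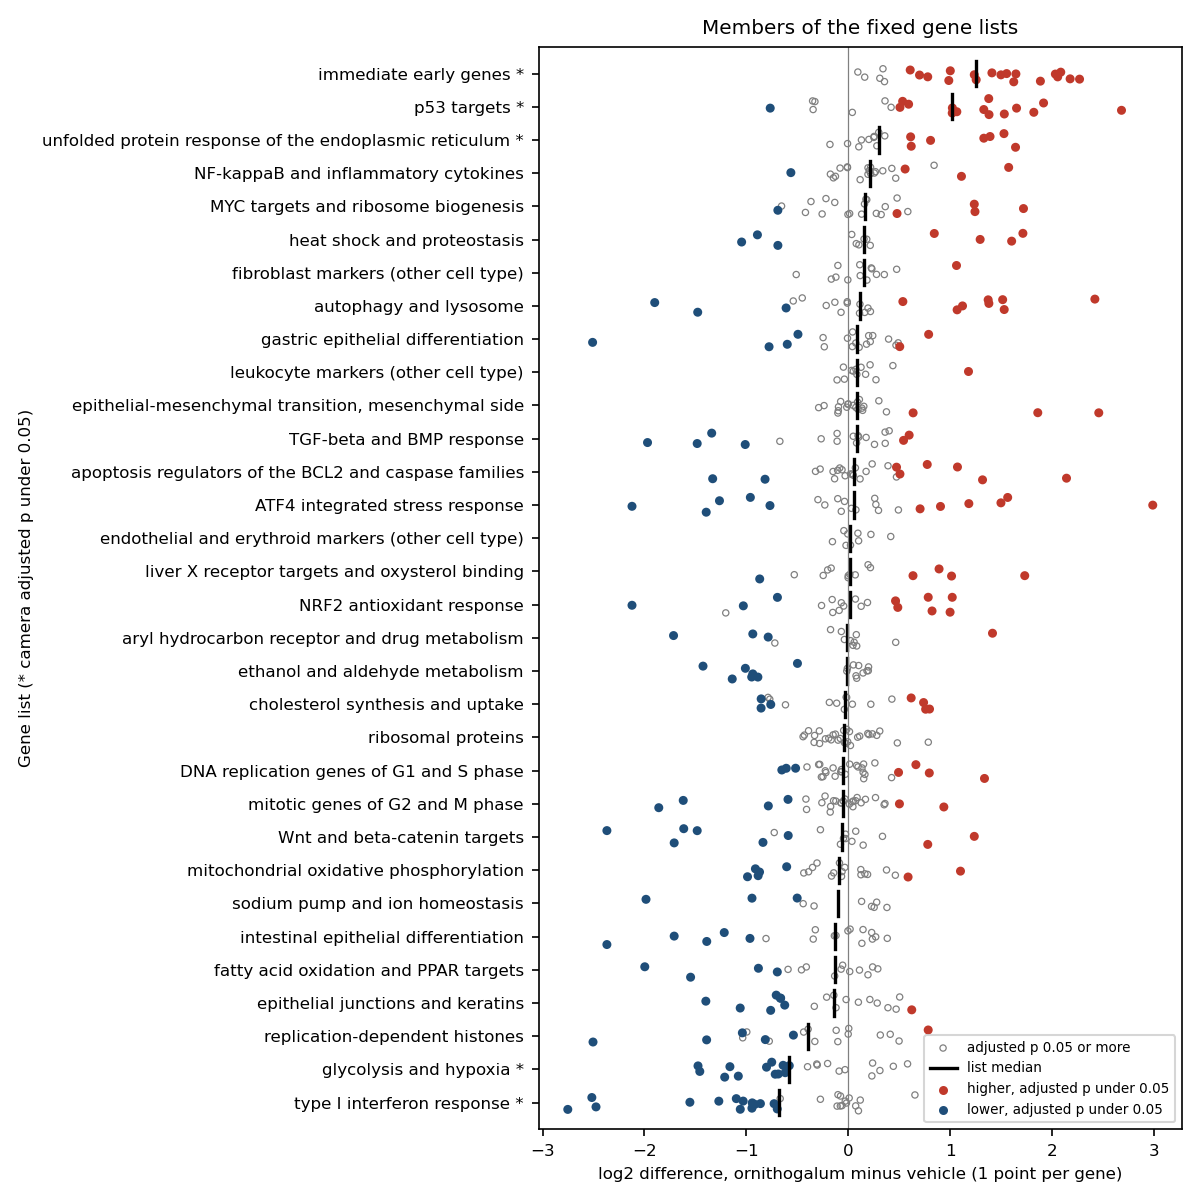
Log2 difference, ornithogalum minus vehicle (x), of each measured member of the 32 gene lists fixed beforehand (y), with a point per gene, list medians as bars and called members filled. The medians of the 5 lists that camera called, marked with an asterisk, lie at 1.26, 1.02, 0.30, -0.58 and -0.68.

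On the deposited values camera called none of the other 27 lists, whose adjusted p ran from 0.081 to 0.99, and their members often went both ways. Other camera settings called the ethanol and aldehyde metabolism, histone and gastric differentiation lists lower and the NF-kappaB and apoptosis lists higher, with adjusted p from 0.013 to 0.045. Among stress lists, 6 of 22 ATF4 targets rose and 5 fell (7 and 5 adjusted over the list alone), with PPP1R15A higher and SLC7A11, the cystine transporter gene, 4.35-fold lower. Heat shock and proteostasis genes rose in 4 and fell in 3 of 13 (4 and 3 adjusted over the list alone), with HSPA4L (3.04-fold) and CHORDC1 (3.28-fold) higher. NRF2 targets rose in 6 and fell in 3 of 20 (6 and 4 adjusted over the list alone), with HMOX1, the haem oxygenase gene, 2.03-fold higher and PGD 2.04-fold lower. Autophagy and lysosome genes rose in 8 and fell in 3 of 23 (8 and 3 adjusted over the list alone), with the autophagy receptor gene SQSTM1 5.36-fold and GABARAPL1 2.89-fold higher and CTSB, a lysosomal protease gene, 3.73-fold lower. Of 26 apoptosis regulators 6 rose and 2 fell (8 and 2 adjusted over the list alone), with PMAIP1, which promotes apoptosis, 4.42-fold and MCL1, which opposes it, 2.10-fold higher and CASP6 2.52-fold lower. In the list of NF-kappaB and cytokine genes 3 of 23 rose and 1 fell (3 and 1 adjusted over the list alone), namely PTGS2 (2.98-fold), LIF (2.16-fold), NFKB2 (1.47-fold) and, lower, TNFAIP2 (1.48-fold). For this list 5 rose and 1 fell without ornithogalum replicate 2, 3 and 0 without replicate 1, and 2 and 0 with the replicate number as a block.

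In the proliferation lists called members were a minority. Mitotic genes rose in 2 and fell in 4 of 29 (2 and 4 adjusted over the list alone), with HMMR (3.63-fold) and ASPM (3.07-fold) lower and CDK1 1.92-fold higher. After median centring 4 mitotic genes rose and 3 fell, with a median of 0.11 against -0.049, and 1 and 3 with the replicate number as a block. DNA replication genes rose in 4 and fell in 3 of 30 (4 and 3 adjusted over the list alone), with RRM2, a ribonucleotide reductase gene, 2.53-fold and PCNA 1.58-fold higher and GINS1 1.57-fold lower. For DNA replication 4 rose and 6 fell without ornithogalum replicate 2, 1 and 1 with the replicate number as a block, and 4 and 0 after median centring. Replication-dependent histone genes rose in 1 and fell in 5 of 19 (2 and 6 adjusted over the list alone), with a median of -0.39 and H2BC14 5.68-fold lower. MYC targets and ribosome biogenesis genes rose in 4 and fell in 1 of 22 (6 and 1 adjusted over the list alone), with ODC1 3.30-fold, RRP12 2.37-fold and MYC itself 2.36-fold higher, while 3 fell without ornithogalum replicate 2 and 0 without replicate 1. Of 30 ribosomal protein genes 0 passed on the deposited values, over all clusters or adjusted over the list alone, with a median of -0.041 that turned positive (0.12) after median centring. RPS24 passed in 7 other settings and RPL3 and RPL32 in 4 each. Without ornithogalum replicate 2, which raised the number of calls, 1 ribosomal protein gene rose and 3 fell, and 2 histone genes rose and 9 fell.

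Among the metabolic lists, ethanol and aldehyde metabolism genes fell in 7 of 17 and rose in 0 (7 and 0 adjusted over the list alone), among them ALDH1B1 (2.20-fold) and CAT, the catalase gene (2.01-fold). Fatty acid oxidation genes fell in 4 of 15 and rose in 0 (4 and 0 adjusted over the list alone), with CPT2 3.99-fold and ACADM 2.92-fold lower. Oxidative phosphorylation genes rose in 2 and fell in 5 of 23 (2 and 5 adjusted over the list alone), with ATP5PO 1.88-fold lower and COX7B 2.15-fold higher. After median centring 4 of them rose and 3 fell, and the list's median went from -0.086 to 0.074. Cholesterol synthesis genes rose in 4 and fell in 3 of 18 (4 and 4 adjusted over the list alone), with SQLE 1.81-fold lower and INSIG1 1.69-fold higher. Liver X receptor and oxysterol-binding genes rose in 4 and fell in 1 of 15 (4 and 1 adjusted over the list alone), with MYLIP 3.32-fold and OSBP 2.02-fold higher. Aryl hydrocarbon receptor and drug metabolism genes rose in 1 and fell in 3 of 14 (1 and 3 adjusted over the list alone), with TIPARP 2.67-fold higher and CYP3A5 3.28-fold lower. Sodium pump and ion homeostasis genes fell in 3 of 10 and rose in 0 (4 and 1 adjusted over the list alone), led by SLC12A2, a sodium, potassium and chloride cotransporter gene, 3.96-fold lower. Without ornithogalum replicate 2, 3 cholesterol genes rose and 5 fell, and 2 aryl hydrocarbon receptor genes rose and 4 fell, and without replicate 1, 4 liver X receptor genes rose and 2 fell.

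Several epithelial and signalling genes were lower. Intestinal differentiation genes fell in 5 of 18 and rose in 0 (6 and 0 adjusted over the list alone), with the stem cell marker LGR5 5.17-fold, LGALS4 3.27-fold and CEACAM5 2.62-fold lower. Epithelial junction and keratin genes fell in 7 of 19 and rose in 1 (7 and 1 adjusted over the list alone), with KRT19 2.63-fold and DSP 1.63-fold lower. The medians of these 2 lists, -0.13 and -0.14, became 0.032 and 0.018 after median centring. Without ornithogalum replicate 2, 3 intestinal genes rose and 7 fell, 4 junction and keratin genes rose and 8 fell, and 5 gastric genes rose and 4 fell. Without replicate 1 the gastric list had 1 higher and 2 lower, and 0 junction and keratin genes rose. Gastric differentiation genes rose in 2 and fell in 4 of 20 (2 and 4 adjusted over the list alone), with MUC1, a surface mucin gene, 5.69-fold lower and SOX2 1.73-fold higher, and the list's median was 0.091, its mean -0.056 and its camera direction up, which turned to down with brighter clusters only (adjusted p = 0.045). Wnt targets fell in 6 and rose in 2 of 18 (6 and 2 adjusted over the list alone), with LGR5, AXIN2 (3.06-fold) and TNFRSF19 (3.27-fold) lower. TGF-beta and BMP response genes fell in 4 and rose in 2 of 19 (5 and 2 adjusted over the list alone), with ID1 3.92-fold and BAMBI 2.53-fold lower, a median of 0.082, a mean of -0.21 and a camera direction down. Of 22 mesenchymal genes 3 rose and 0 fell (3 and 0 adjusted over the list alone), namely MMP1 (5.50-fold), CCN1 (3.63-fold) and THBS1 (1.56-fold).

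Few markers of other cell types passed. Of 14 fibroblast markers 1 rose (PDGFRA, 2.08-fold), of 13 leukocyte markers 1 rose (CD68, 2.26-fold), and of 9 endothelial and erythroid markers 0 passed, with the same counts adjusted over the list alone. The medians were 0.15, 0.085 and 0.022, the last of which turned to -0.0037 after cyclic loess. Without ornithogalum replicate 1 they were 0.034, 0.069 and 0.14, and without replicate 2 they were 0.22, 0.097 and -0.050. Over all 36 markers the median log2 difference was 0.099 (95% bootstrap interval 0.022 to 0.184), which lay 0.063 above the median of all clusters, before and after median centring. Without ornithogalum replicate 2, 3 fibroblast, 2 leukocyte and 1 of the endothelial and erythroid markers rose, and without replicate 1, 1 fibroblast marker fell.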

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

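This count was taken from the planned fit over every cluster of the table after that fit had been seen. Among 12083 clusters with no gene name in the annotation used here, which the report leaves out and which were tested only together with all other clusters of the table, limma called 504 as changed, 273 higher and 231 lower. The same fit called 2644 of all 33297 clusters, with 2140 among the 21214 named ones, a larger share than among those without a name. The count drew attention as a signal in data outside the named clusters. Their median log2 value was 3.62 and 3.61 on the ornithogalum arrays and 3.48 and 3.49 on the vehicle arrays, the opposite order to the named clusters. Named clusters of mean log2 value up to 3 also had positive median differences from vehicle, 0.296 and 0.087 on ornithogalum arrays 1 and 2. Those from 5 to 6 had -0.211 and -0.069, so the order varied with brightness and is not particular to clusters without a name. No explanation was tested.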

How the results depend on the processing

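Only the array weights (4073 clusters, 1350 higher and 2723 lower) were chosen after the results were seen. The number of called clusters, 4076, stayed within 1.5 times under the 3 scalings, the intensity trends, brighter clusters only, single-symbol clusters and the looser or size-bound thresholds. Leaving out an array gave 0 to 7058 called clusters, 0 to 3054 higher, 0 to 4004 lower and 3986 to 9839 at an unadjusted p under 0.05. The 0 came without either vehicle array, where the lone vehicle array is assumed to vary like the ornithogalum pair and the smallest adjusted p was 0.0605 and 0.0612. Without moderation of the variance 2 clusters passed, since 2 residual degrees of freedom are left. Testing all 33297 clusters called 2644 and 1677 lower. Median centring gave 2238 higher, and the percent of calls that were lower, 65.8, became 56.0 after quantile scaling, 60.2 after cyclic loess and 45.9 after median centring. Separation by at least 1.2-fold held for 5990 clusters and by at least 2-fold for 1055. Camera called 8 lists with brighter clusters only and 0 with an estimated correlation, and fry, which does not compare a list with other genes, called 24. Of lists not called in the report, camera called ethanol and aldehyde metabolism lower after quantile scaling (adjusted p = 0.024), cyclic loess (0.033) and with brighter clusters (0.013), histones lower with the block (0.041) and after median centring (0.033), NF-kappaB higher after quantile scaling (0.039) and cyclic loess (0.041), and apoptosis regulators higher with brighter clusters (0.045). The 5 lists called in the report kept their call in 13 of 14 other settings. The gastric differentiation list turned to down with brighter clusters only (adjusted p = 0.0447) and with fry (adjusted p = 0.0345), and PECAM1, which did not pass, turned to 0.0048 after median centring. With the replicate number as a block, 3302 clusters were called, 1035 higher and 2267 lower, and 6 lists. PCNA, NFKB2 and ATP1B1 lost their call there, ATP1B1 also without ornithogalum replicate 1 (adjusted p = 0.058), GINS1 and ATP1B1 after median centring, and these 4 with HADHB, THBS1, SOX2 and PSCA when all clusters were tested. Genes not called in the report passed elsewhere, RPS24 in 7 settings, RPL3 and RPL32 in 4 each, ACTA2 in 2, and CD4 and TEK in 1, without ornithogalum replicate 2. Same-numbered arrays did not deviate together (correlation -0.059), which gives no sign that the numbers pair the samples but does not exclude it. The cause of these shifts was not tested unless stated. Camera with a robust prior was not run. No signal over background is given, so its limit on dim clusters is unknown.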

Other observations

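Of the tests in this part, the matched random lists for the interferon genes and the median of further NFAT5 targets had their bounds written before their outcome was seen, and the 13 gene families and the other 7 tests of explanations were chosen after. The adjustment over these families, given for camera with the preset and with the estimated correlation, covers all 13 but not the reading of the ranked genes that prompted them, so their p-values describe these arrays only.

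Genes of the circadian clock changed in 11 of 18 measured, 9 higher and 2 lower, with a median log2 difference of 0.67. NR1D1 and PER1 were joined by CRY1 (3.91-fold higher), NFIL3 (3.16-fold) and BHLHE40 (2.88-fold), while PER3 (1.69-fold) and CLOCK were lower (9 and 2 adjusted over the family alone, camera adjusted p = 0.00023, adjusted p = 0.22 with an estimated correlation). Feedback and output genes of the ERK pathway rose in 10 of 17 and fell in 0, with DUSP6 4.83-fold, EPHA2 4.19-fold and SPRY4 3.13-fold higher (11 and 0 adjusted over the family alone, adjusted p = 9.7e-07, adjusted p = 0.22 with an estimated correlation). Of the risers, DUSP6, SPRY4, FOSL1 and IER3 are also members of the immediate early list, so this family is not separate from it. FOXO targets and arrestin-domain genes rose in 14 of 31 and fell in 1, ERBB3, with KLHL24 5.34-fold and ARRDC4 3.92-fold higher (15 and 1 adjusted over the family alone, adjusted p = 9.7e-07, adjusted p = 0.22 with an estimated correlation). A short list of 5 death receptor genes, which does not cover all such receptors, had 4 measured, and all 4 rose (4 adjusted over the family alone, adjusted p = 5.9e-05, adjusted p = 0.22 with an estimated correlation). The decoy receptor gene TNFRSF10D, whose product lacks a working death domain, rose 5.83-fold and TNFRSF10A 2.49-fold. FAS and TNFRSF10B, also in this list, were already counted among the p53 targets. Other members counted before include SESN1 (p53) and GABARAPL1 (autophagy) in the FOXO family, and CAT (ethanol metabolism) in the peroxisome family. DNA repair genes fell in 10 of 23 and rose in 2, with RAD50 5.46-fold, BRCA1 3.09-fold and NBN 2.87-fold lower (11 and 2 adjusted over the family alone, adjusted p = 0.00027, adjusted p = 0.26 with an estimated correlation). Peroxisome genes fell in 4 of 11, namely HSD17B4, CAT, ACOX3 and PEX3 (5 lower and 2 higher adjusted over the family alone, adjusted p = 0.025, adjusted p = 0.26 with an estimated correlation). Camera no longer called the peroxisome family without ornithogalum replicate 2 (0.0503; 2 higher and 5 lower) or without vehicle replicate 1 (0.0508), while it called the other 5 of these families without any single array. With an estimated correlation 0 of the 13 families passed. NR1D1, PER1, ARRDC3, GADD45A and other members of these families were known to be among the largest changes when the families were drawn up.

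Camera did not call the next 5 families. Targets and factors of nonsense-mediated decay rose in 5 and fell in 2 of 14 (6 and 2 adjusted over the family alone, camera adjusted p = 0.086), with 156 of 10000 matched random lists as high. This family mixes transcripts that the pathway degrades with its own factors, so the counts give no direction for the pathway. GADD45A, which rose, is also in the FOXO family. In the citric acid cycle family SUCLA2 rose and 5 of 17 fell, the mitochondrial SDHC, IDH2 and IDH3G and, not part of the cycle itself, the cytosolic IDH1 and MDH1 (1 and 5, adjusted p = 0.25). EGF family genes rose in 3 and fell in 2 of 6 (3 and 2, adjusted p = 0.42), with 59 of 10000 random lists as high. SR splicing factors and their kinases rose in 7 and fell in 2 of 24 (8 and 6 adjusted over the family alone, adjusted p = 0.60), with CLK1 4.32-fold higher. Zinc finger genes rose in 38 and fell in 66 of 521 (39 and 68, adjusted p = 0.36), and 0 of 1000 matched random lists had a median as low as theirs, -0.044. Without ornithogalum replicate 2, 81 zinc finger genes rose and 113 fell, and 7 SR genes rose and 4 fell. Odorant and taste receptors, keratin-associated proteins and defensins, which are dim here, rose in 17 of 482 and fell in 0, with a median of 0.21 (adjusted p = 5.9e-05, adjusted p = 0.29 with an estimated correlation), but 0 passed when adjusted over that family alone. Named clusters of mean log2 value up to 3 had median differences of 0.296 and 0.087 on ornithogalum arrays 1 and 2. Of 1000 matched random lists, 2 had a median as high as this family. The median of these genes was 0.096 without ornithogalum replicate 1 and 0.28 without replicate 2. Without ornithogalum replicate 2, 119 of these rose and 14 fell, and without replicate 1, 19 and 3.

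The number of changed clusters was large, and without the first ornithogalum array, which had the narrowest distribution, 4322 were called, but the spread then comes from the vehicle pair alone, so that count decides nothing about the array. After quantile scaling, which gives the arrays 1 distribution, 4125 were called, which argues against unequal distributions as the whole cause. Cells of another type would raise their markers together, and the median of the 36 markers was 0.099 with an upper bootstrap bound of 0.184. Relative to the median of all clusters that bound was at most 0.148 on the deposited values and after each of 3 scalings, which argues against a joint rise of all these markers. No cell type holds most of the 36 markers, so a rise in a single type could leave this median low. By type the medians were 0.15 for fibroblast, 0.085 for leukocyte and 0.022 for endothelial and erythroid markers. No bound was set by type, so cells of a single other type are not excluded. Differences between the culture wells other than the treatment stay open, because each group holds its own cultures.

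More clusters were lower than higher. A first test asked whether the excess outlasted quantile scaling and the loss of the first ornithogalum array, and at least 56.0% of calls stayed lower. Once median centring was seen to give 45.9%, the test was widened to 3 scalings, and the excess then did not hold in each. Unequal distributions, scaling and a true excess of falls cannot be told apart here, since no value within the arrays fixes the zero point.

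The interferon response genes were lower by a median of -0.68, and 0 of 10000 random lists of like brightness reached that, which argues against compression acting on all such genes. Without the first ornithogalum array camera still gave an adjusted p = 0.00016, and the list's median was -0.62. Loss of a small share of leukocytes was tested through 13 leukocyte markers, whose median was 0.085, but these lie near the floor, at a median percentile of 29.4 of vehicle values, so they decide nothing, although a first reading of this test had counted them against it. AGS is an established cancer line, so any leukocytes would be contaminants and not a regular part of the cultures. The values neither show nor exclude such a share, and a treatment effect on interferon signalling also stays open.

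NFAT5, the regulator of the response to high tonicity, rose 3.82-fold, and the osmolyte transporter gene SLC5A3 rose 3.75-fold. SLC38A2, an amino acid transporter gene, rose 3.89-fold. A tonicity response could account for these, and 5 further NFAT5 targets had a median of -0.015, under the bound written beforehand. Their median was 0.18 without ornithogalum replicate 1 and 0.022 without replicate 2, still under that bound. That bound was ill chosen, because 3 of the 5 lie below the median vehicle value. The brighter SGK1 rose 1.67-fold and SLC6A6 differed by 0.49 on the log2 scale (limma adjusted p = 0.058, past the threshold when adjusted over the family alone), so the explanation stays open.

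A loss of long transcripts through slowed elongation could also lower many genes. Across 18389 genes, which are not independent, gene length and log2 difference had Spearman's rho of -0.056, which argues against it as an account of the changes as a whole. THAP1 (6.07-fold higher) and RNF170 (6.08-fold lower) are neighbouring protein-coding genes on chromosome 8 and changed in opposite directions, a pair picked after their values were seen.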
